A study of Arabidopsis thaliana with 13 samples.

How the data were processed

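Polyadenylated RNA of whole dark-grown Arabidopsis thaliana seedlings was sequenced in 13 libraries. Wild-type Col-0 seedlings treated with the solvent (mock), with pifithrin-alpha (PFT-alpha) or with ACC gave 3 libraries each. Seedlings of etr1-1, which carry an altered form of the ethylene receptor ETR1 that makes them insensitive to ethylene, gave 2 mock and 2 PFT-alpha libraries. The series describes 3 replicates per treatment, and 2 were listed for each etr1-1 group. Groups and replicate numbers were taken from the labels before the data were examined.

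The deposited table held TPM (transcript abundance scaled by length and depth) for 33033 genes, with the libraries' values beside 5 columns of group means that were not used. TPM, named so per the file headers, divides each gene's fragments by its length and scales each library to the same total, and the column sums bore this out. Per the submitters' processing notes, fastp, HISAT2, HISAT, StringTie, RSEM and DESeq2 were used on the TAIR10 build, with neither versions nor the role of each tool given. Libraries were made with a stranded kit, per the labels' protocols, but whether the counting used strand is not stated. Counts were not used here, so no count model was fitted. Low TPM values multiplied by length fell on steps of 1 fragment (81.5 to 86.7% within 0.15 of a whole step), which gave estimated depths of 20.5 to 29.3 M fragments. At these depths 1 TPM of a 1500-base transcript stood for 19.8 to 29.0 fragments.

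Gene symbols came from the table, and 15 were added from a reference gene table of the TAIR10.1 assembly, in which 32548 of the identifiers were found. That table served for names, and exon positions and strands of a reference annotation served to find which genes overlap. Of the tested genes, 1057 lay over an antisense gene for at least 50% of their length and 6974 overlapped another gene at all, and values of such genes are uncertain because strand use is unknown. The deposited table also held 200 gene models assembled by the authors, of which 193 were tested, and 1734 features shorter than 200 bases, whose TPM rest on few fragments in size-selected libraries.

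Values were analysed as log2(TPM + 1), so fold changes of low genes are understated. Genes with at least 1 TPM in at least 2 libraries were tested (21091 genes), 6724 genes were at 0 in all libraries, and 11942 were left out. The planned fit was limma 3.58.1 in R 4.3.3 with an intensity trend, all 13 libraries and a mean per group, with two-sided tests and Benjamini-Hochberg adjustment over the tested genes at 0.05. The 6 planned comparisons were PFT-alpha against mock, ACC against mock and PFT-alpha against ACC in wild type, etr1-1 against wild type in mock, PFT-alpha against mock in etr1-1, and the genotype by PFT-alpha interaction. Scaling by median of ratios or quantiles moved the median fold change of all genes by less than 0.1. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

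Replicate numbers were taken to pair the wild-type libraries. Deviations from the group means correlated between same-numbered wild-type libraries at 0.28 to 0.77 across genes in all 9 pairs, while same-numbered wild-type and etr1-1 libraries gave -0.22 to 0.24 and the etr1-1 pairs 0.13. Replicate 3 gave 0.70 to 0.77. Same-numbered wild-type libraries 1 and 2 gave 0.28 to 0.55, and wild-type libraries 1 and 2 of different number 0.29 to 0.54, so the data do not tell pairs 1 and 2 apart. No label says what the numbers share. The shared shift of replicate 3 is a finding from the data, while the pairing of replicates 1 and 2 is an assumption. The planned, paired and reduced fits do not pair the mutant libraries, while the block fit does. Other fits beside the planned one are named in the text. The block fit, planned before the data were examined, takes the replicate number as a factor over all 13 libraries. The paired fit, chosen after the data were seen, takes it over the 9 wild-type libraries alone. The reduced fit, also chosen after the data were seen, leaves out the library labelled etr1-1 mock 1, which resembled ACC-treated wild type, and holds a batch term for wild-type replicate 3, which stood apart from the other libraries. In the reduced fit mock-treated etr1-1 is 1 library, assumed to vary like the other groups.

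Lists of genes (23 in all) on hormones, light, growth, stress, detoxification and tissues were fixed from textbook knowledge before the data were examined. Of their 379 entries, 374 matched a locus and symbol, 4 matched by locus and 1 was moved to another locus by the fixed matching rule. That entry, ACO3, was meant as an ethylene-forming oxidase and became AT2G05710, an aconitase. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01 over 138 tests of 23 lists in 6 comparisons, with camera at an estimated correlation and fry as alternatives. With an estimated correlation 0 of 138 tests were called (adjusted p = 0.637 to 0.999), and fry, which asks whether a list's genes move 1 way on balance, called 0. The estimate came from residuals that hold the replicate 3 shift and the difference between the etr1-1 mock libraries. It was 0.69 for ethylene-induced genes, and even their rise under ACC, with 19 of 20 above 0, stood at an adjusted p of 0.637. A call lost with an estimated correlation therefore does not show that a list is unchanged. Overlapping lists are not independent. Enrichment was tested for gene ontology terms of the authors' annotation in the deposited data (1026 terms of 10 to 500 genes, 16537 background genes that were tested and annotated). It used Fisher's exact test adjusted over 6156 tests, and was chosen after the data were seen.

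Genes named in the text followed a rule fixed before the data were examined. It took, per comparison, up to 6 called genes with the highest and 6 with the lowest fold change, at least 5 TPM and no overlap between groups, the 3 members with the smallest adjusted p from up to 6 lists, 5 genes for the interaction, and in every comparison ETR1, ETR2, ERS1, ERS2, EIN4, EBF2 and ERF1. Where the planned fit called too few genes, the same rule was applied to the paired or reduced fit. AT2G44130, AT3G13310, MYB4, RIPK and their relatives were chosen after their values were seen, as were called genes outside the rule. On data simulated from these libraries for PFT-alpha against mock in wild type, the planned fit recovered 6% of genes changed 1.5-fold, 46.3% changed 2-fold and 80.3% changed 4-fold with 1 false call. The paired fit recovered 34.3%, 71.6% and 95.5% with 7 false calls. For PFT-alpha against mock in etr1-1 the planned fit recovered 1.5%, 28.4% and 72.7% with 0 false calls. All simulated groups had the wild-type mean, the spread of the paired fit and, in wild type, the shift of replicate 3. The difference between the etr1-1 mock libraries was left out, and changed genes were drawn from those at about 5 TPM or more. The shares can therefore overstate what the planned fit recovers in the real data.

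Alternatives tried were pseudocounts of 0.1 and 5, no filter or 5 TPM, median-of-ratios and quantile scaling, fits of the compared groups alone, no trend, library weights, stricter thresholds, and leaving out each library in turn. Fits with a batch term for wild-type replicate 3, without those 3 libraries, and without the library labelled etr1-1 mock 1 were added after the data were seen.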

Results

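Transcript levels were measured by RNA sequencing in whole Arabidopsis seedlings that had 6 h of white light and then grew in darkness at 22 °C. At 4 days they spent 4 h in liquid medium with 30 µM PFT-alpha, 10 µM ACC or 1‰ DMSO as the mock. PFT-alpha is a small molecule known as an inhibitor of the animal tumour suppressor p53, and ACC is the compound from which plants make ethylene. Wild type gave 3 libraries each of mock, PFT-alpha and ACC, and the ethylene-insensitive receptor mutant etr1-1 gave 2 each of mock and PFT-alpha. Estimated depth was 20.5 to 29.3 M fragments, and 19059 to 19865 genes per library reached 1 TPM.

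ETR1 itself measured 21.8 ± 4.09 TPM in wild-type mock, 22.4 ± 2.55 under PFT-alpha and 23.8 ± 3.45 under ACC (SD, n = 3 each), and 22.4 ± 3.58 in mock and 23.5 ± 0.919 under PFT-alpha in etr1-1 (SD, n = 2 each). The etr1-1 allele is an amino acid change in the receptor, so these values do not check the genotype labels. ERS2, another ethylene receptor gene, measured 46.89 TPM in the library labelled etr1-1 mock 1 and 11.04 in etr1-1 mock 2. It measured 45.36 to 50.43 TPM under ACC in wild type. Replicate 3 of all 3 wild-type groups lay apart on PC1 at 74.35 to 86.98, against -35.18 to -9.54 for the other 10 libraries. PC1 carried 44.7% of the variance and PC2 18.5%.

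**Figure D1:**
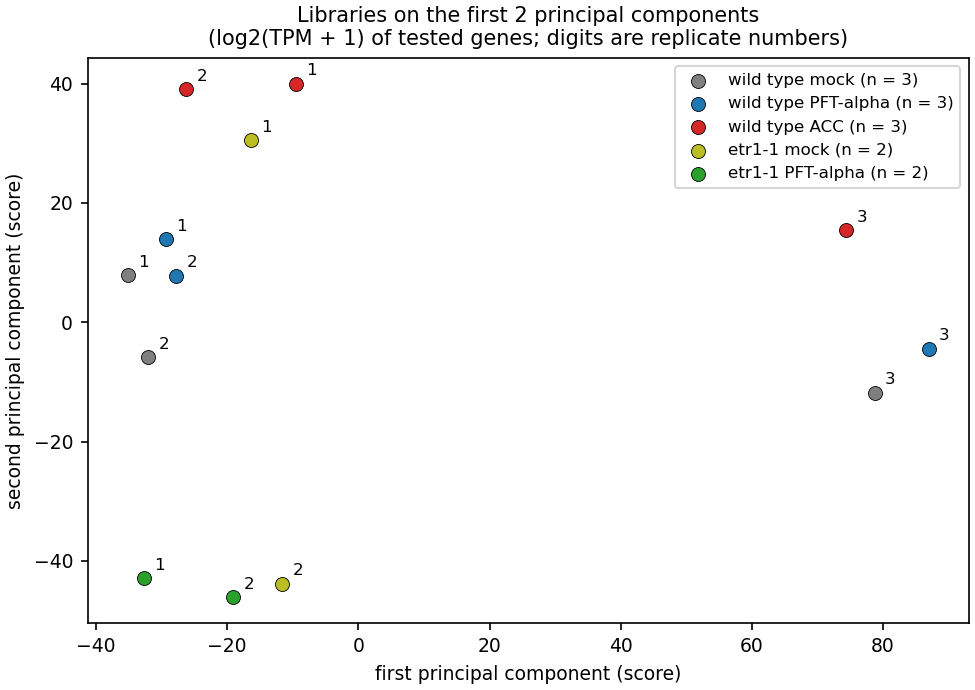
Each point is a library placed by its scores on PC1 and PC2 of log2(TPM + 1), coloured by group, with the replicate number beside it. The 3 wild-type replicate 3 libraries lie at 74.35 to 86.98 on PC1, and the library labelled etr1-1 mock 1 lies near the ACC-treated wild type on PC2 rather than with the other 3 etr1-1 libraries.

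ACC against mock in wild type served as the reference for an ethylene response. In the paired fit of the 9 wild-type libraries, chosen after the data were seen, RTE1, a membrane protein that acts with ETR1, rose from 10.3 ± 0.448 to 34 ± 3.92 TPM (SD, n = 3 each, log2 1.62, SE 0.13, adjusted p = 0.00176). HLS1, needed for the apical hook of dark-grown seedlings, rose from 36.4 ± 4.95 to 96.9 ± 10.9 TPM (log2 1.39, SE 0.12, adjusted p = 0.00204). ORS1, a regulator of organ size, rose from 12.4 ± 3.81 to 99.2 ± 16.1 TPM (log2 2.93, SE 0.21, adjusted p = 0.00112). The transcription factor gene ERF1, a direct target of the ethylene pathway, rose from 1.65 ± 1.26 to 8.89 ± 3.01 TPM (log2 1.98, SE 0.17, adjusted p = 0.00199). Of the other receptor genes ERS2 (log2 1.67, adjusted p = 0.00228), ERS1 (0.79, 0.00496) and ETR2 (0.81, 0.0196) rose. EBF2, which marks the factor EIN3 for degradation (0.61, 0.0113), and CTR1, the kinase below the receptors (1.22, 0.00078), also rose. For RTE1, HLS1, ORS1 and ERF1 the adjusted p was 0.152 to 0.254 in the planned fit and 0.0332 to 0.0526 with the replicate block, where ERF1 lost its call. ERS2 was called with the block (adjusted p = 0.0401), and ERS1 (0.0744), ETR2 (0.155), EBF2 (0.0886) and CTR1 (0.094) were not. In the planned fit these 5 stood at 0.189 to 0.527. EIN4 differed by -0.02 (adjusted p = 0.975) and ETR1 by 0.13 (adjusted p = 0.505).

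Auxin-responsive IAA6 fell in the paired fit, from 29.6 ± 10.7 to 3.81 ± 1.2 TPM (SD, n = 3 each, log2 -2.63, SE 0.20, adjusted p = 0.00135). The auxin-responsive SAUR19 and AT5G18030 fell by 1.32 and 1.03 (adjusted p = 0.00563 and 0.0223). BR6OX1, which makes brassinosteroids, fell by 1.22 (adjusted p = 0.00473). The gibberellin synthesis genes GA3OX1 and GA20OX1 fell by 0.77 and 0.84 (adjusted p = 0.0131 and 0.0396). The shade avoidance transcription factor genes HB-2 and HAT2 fell by 0.72 and 0.59 (adjusted p = 0.0141 and 0.0317), and PAR2 by 1.21 (adjusted p = 0.0128). For these 9 genes the adjusted p was 0.122 to 0.227 in the planned fit. With the replicate block GA20OX1 lost its call (adjusted p = 0.0532) and the others stood at 0.0189 to 0.03. Apart from the short ath-MIR838, the largest rises among genes named by the rule were EXPA12, an expansin, from 3.43 ± 0.246 to 59.1 ± 10.8 TPM (log2 3.75, adjusted p = 0.000572), ORS1, ADS1 (2.18), CYP718 (2.14) and GH9B12 (2.05). The microRNA precursor ath-MIR838, a short feature, was listed at 0 in all 3 mock libraries and at 7.19 ± 3 TPM under ACC (n = 3, adjusted p = 0.016). Apart from IAA6 and the short ath-MIR4228, the largest falls were AGP22, from 377 ± 135 to 47.9 ± 16.5 TPM (log2 -2.93, adjusted p = 0.00199), EXPA5 (-2.84), EXPB1 and RAB7A (-2.54). EXPB1 went from 27.6 ± 3.52 to 3.57 ± 0.546 TPM (-2.65, adjusted p = 0.000483).

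By list, 16 of 20 ethylene-induced genes rose in the paired fit, and 18 rose and 1 fell when adjusted over the list alone. Their median in the planned fit was 1.03 log2, with 19 of 20 above 0 (camera adjusted p = 1.32e-16, adjusted p = 0.637 with an estimated correlation). Of 26 auxin-responsive genes 1 rose and 10 fell, and 1 and 16 adjusted over the list alone (median -0.71, adjusted p = 9.33e-09, adjusted p = 0.821 with an estimated correlation). Of 17 gibberellin and brassinosteroid genes 6 fell, and 7 adjusted over the list alone (median -0.41, adjusted p = 0.000192, adjusted p = 0.637 with an estimated correlation). Of 20 shade avoidance and PIF-regulated genes 2 rose and 8 fell, and 3 and 9 adjusted over the list alone (median -0.25, adjusted p = 0.00233, adjusted p = 0.637 with an estimated correlation). Of 15 perception genes 7 rose, and 7 adjusted over the list alone (median 0.22, adjusted p = 0.000345, adjusted p = 0.821 with an estimated correlation). Of 11 low oxygen genes 1 rose, LBD41 at 0.80 (adjusted p = 0.042, and 0.269 with the block), and 4 adjusted over the list alone (median 0.83, adjusted p = 0.000118, adjusted p = 0.964 with an estimated correlation). Of 18 cell wall expansion genes 1 rose and 2 fell, and 2 and 7 adjusted over the list alone (median -0.31, adjusted p = 0.0488, adjusted p = 0.988 with an estimated correlation). With the replicate block 7 ethylene-induced genes rose, 11 auxin-responsive and 4 gibberellin and brassinosteroid genes fell, 1 shade gene rose and 4 fell, 2 perception genes and 0 low oxygen genes rose, and 1 cell wall gene rose and 2 fell. In the planned fit 0 members of these 7 lists were called over all genes. Adjusted over the list alone, it called 13 ethylene-induced and 2 perception genes as higher, 10 auxin-responsive, 4 gibberellin and brassinosteroid and 2 cell wall genes as lower, 1 shade gene as higher and 7 as lower, and 0 low oxygen genes. The cell wall list's call was lost with the replicate block (adjusted p = 0.05), and without mock 1 (-0.22), mock 2 (-0.21), ACC 1 (-0.31) or ACC 3 (-0.11), and the shade call without ACC 1 (-0.15). With the block, antenna and Rubisco genes (0.20, adjusted p = 0.0205) and xenobiotic genes (0.18, adjusted p = 0.034) were also called as higher (adjusted p = 0.864 and 0.788 with an estimated correlation, and adjusted p = 0.159 and 0.134 in the planned fit).

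The planned fit called 2 genes under ACC, both lower, with 1769 genes at an unadjusted p under 0.05 where chance gives 1055. AT5G61570 fell from 20.1 ± 1.26 to 4.26 ± 0.861 TPM (SD, n = 3 each, log2 -2.01, SE 0.23, adjusted p = 0.0413). The microRNA precursor ath-MIR4228, a short feature, was listed at 0 in all 3 ACC libraries and at 55.4 ± 53.6 TPM in mock (adjusted p = 0.0413). With the replicate block over all libraries 710 genes were called, 171 higher and 539 lower, and the paired fit called 1159, 331 higher and 828 lower, of which 389 changed at least 2-fold. The etr1-1 mock libraries are in neither group, but their difference enters the shared spread. Without the library labelled etr1-1 mock 1 the planned fit called 364 genes, and without etr1-1 mock 2 it called 356. The count was 0 without wild-type mock 2, ACC 2 or ACC 3 and 1 without wild-type mock 3. The call of AT5G61570 was lost without any 1 of the 6 libraries (-1.87 to -2.09). For ath-MIR4228, ACC vs mock in wild type lost its call without mock 2 (-5.69), ACC 1, ACC 2 or ACC 3 (-5.41 each). In 2597 genes (12.3%) the groups did not overlap, where chance gives 10% for exchangeable libraries. Replicate 3 stood apart in both groups, so these libraries were not exchangeable.

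**Figure D2:**
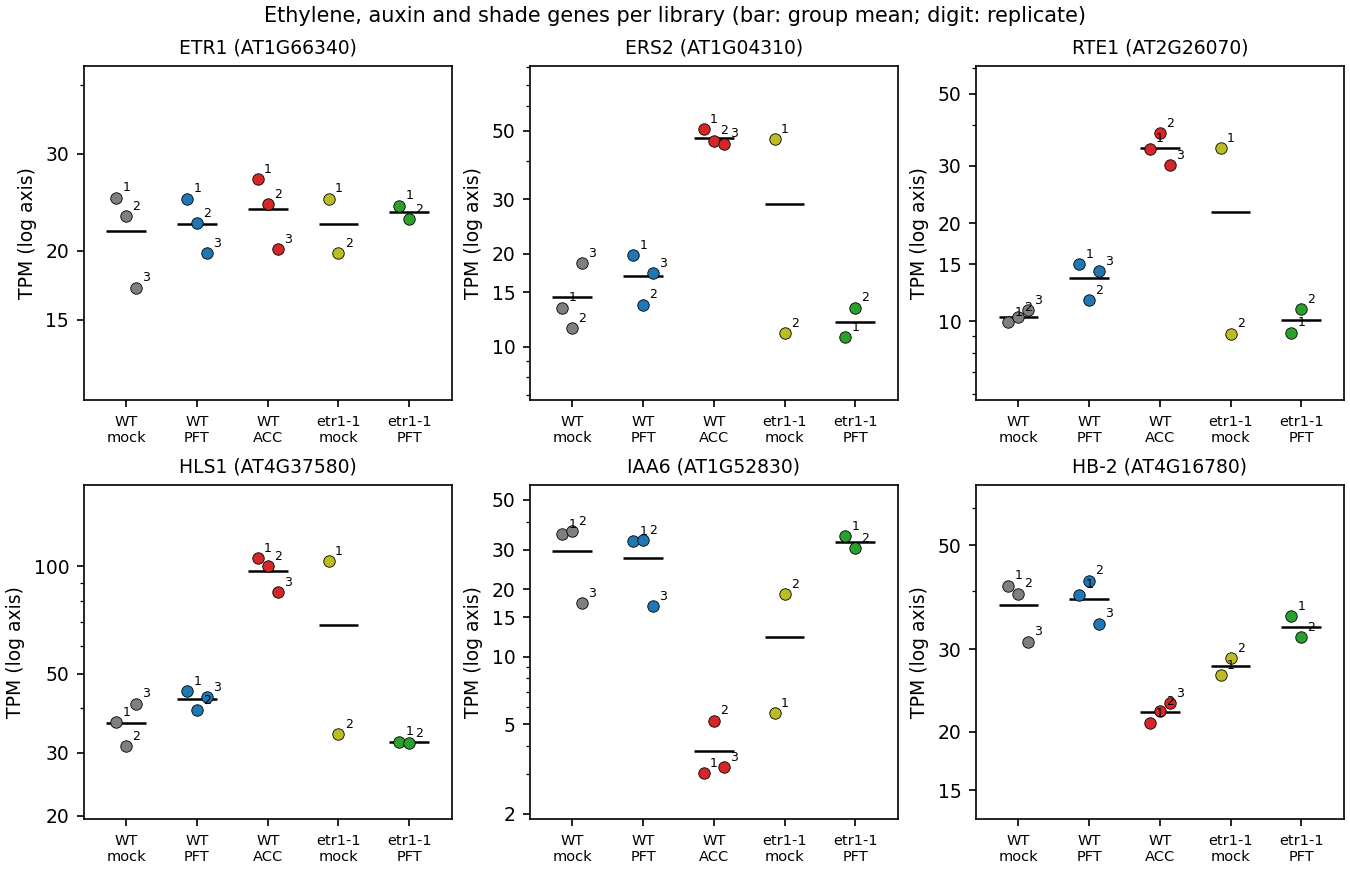
TPM per library on a log axis for ETR1, ERS2, RTE1, HLS1, IAA6 and HB-2, by group, with the group mean as a bar and the replicate number beside each point. ERS2, RTE1 and HLS1 are higher and IAA6 and HB-2 lower in the 3 ACC libraries than in the 3 wild-type mock libraries, and the library labelled etr1-1 mock 1 lies near the ACC libraries.

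PFT-alpha against mock in wild type asks what the small molecule does on its own, since the series reports it as acting on ETR1. ARL, a relative of ORS1, measured 144 ± 40.8 TPM in mock and 201 ± 23.8 under PFT-alpha (SD, n = 3 each, log2 0.51, SE 0.15, adjusted p = 1 in the paired fit). RTE1 measured 10.3 ± 0.448 and 13.6 ± 1.78 TPM (0.36, SE 0.13, adjusted p = 1). ERS2 differed by 0.22, ETR2 by 0.18, ERS1 by 0.03, EIN4 by -0.11, EBF2 by 0.08 and ERF1 by 0.36 (adjusted p = 1 for each). GSTU3, a glutathione transferase of the kind that conjugates foreign compounds, measured 1.14 ± 0.81 and 4.1 ± 2.73 TPM (1.12, SE 0.27, adjusted p = 1). The shade gene HB-2 measured 37.2 ± 5.28 and 38.4 ± 4.06 TPM.

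As lists, low oxygen genes rose (median 0.41, 10 of 11 above 0, camera adjusted p = 0.000786, adjusted p = 0.988 with an estimated correlation). Xenobiotic detoxification genes rose as well (0.15, 22 of 27 above 0, adjusted p = 0.00126, adjusted p = 0.988 with an estimated correlation). Ethylene-induced genes rose by a median of 0.17 (18 of 20 above 0, adjusted p = 0.0029, adjusted p = 0.999 with an estimated correlation). Antenna and Rubisco genes rose by 0.19 (18 of 18, adjusted p = 0.0106, adjusted p = 0.999 with an estimated correlation). Seed storage and oil body transcripts, remnants of the embryo, fell by a median of 1.18 (1 of 11 above 0, adjusted p = 0.00227, adjusted p = 0.988 with an estimated correlation). SESA2 among them measured 113 ± 107 TPM in mock and 45.3 ± 76.5 under PFT-alpha (n = 3 each). No member of these lists was called over all genes or adjusted over the list alone in the planned fit, and in the paired fit 6 seed storage genes fell adjusted over the list alone. In wild-type replicate 3, antenna and Rubisco genes lay 1.13, 1.41 and 1.06 log2 above the other replicates in mock, PFT-alpha and ACC. Seed storage genes lay 1.70, 2.67 and 3.33 above them. The planned fit has no replicate term, so leaving out 1 wild-type library weighs the replicate 3 shift unequally between groups. Medians from such fits, here and in the other comparisons, hold part of that shift. In them each of these 5 list calls was lost without at least 1 library. Low oxygen genes then stood at 0.23 without mock 2, 0.31 without mock 3 and 0.12 without PFT-alpha 1, and ethylene-induced genes at -0.02 without mock 3 and 0.06 without PFT-alpha 1. Xenobiotic genes stood at -0.11 without mock 3 and at -0.03 and -0.02 without PFT-alpha 1 and 2, and seed storage genes at -0.45, -0.82 and -0.78 without the same libraries. Antenna and Rubisco genes stood at -0.02 and 0.02 without mock 1 and 2, and tested as down at -0.27 without PFT-alpha 3. Shade avoidance genes had a median of -0.05 but tested as up by camera (adjusted p = 0.852), and auxin-responsive genes a median of 0.05 (adjusted p = 0.144).

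By limma 0 genes were called for PFT-alpha in wild type in the planned fit (147 at an unadjusted p under 0.05, smallest adjusted p 1), 0 with the block (674), 0 in the paired fit (817) and 0 in the reduced fit (1166, smallest adjusted p 0.166). Chance gives 1055 genes at that unadjusted threshold, and 147, 674 and 817 lie below it. The 0 calls therefore do not show that PFT-alpha has no effect. Without wild-type mock 1 the planned fit called 2 genes, and without wild-type PFT-alpha 3 it called 1. For PFT-alpha vs mock in wild type, limma with library weights called 606 genes, a fit without the 3 wild-type replicate 3 libraries 3, and a fit without those and the library labelled etr1-1 mock 1 called 6. In 770 genes (3.65%) the groups did not overlap, where chance gives 10% for exchangeable libraries, which these were not with replicate 3 apart.

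**Figure D3:**
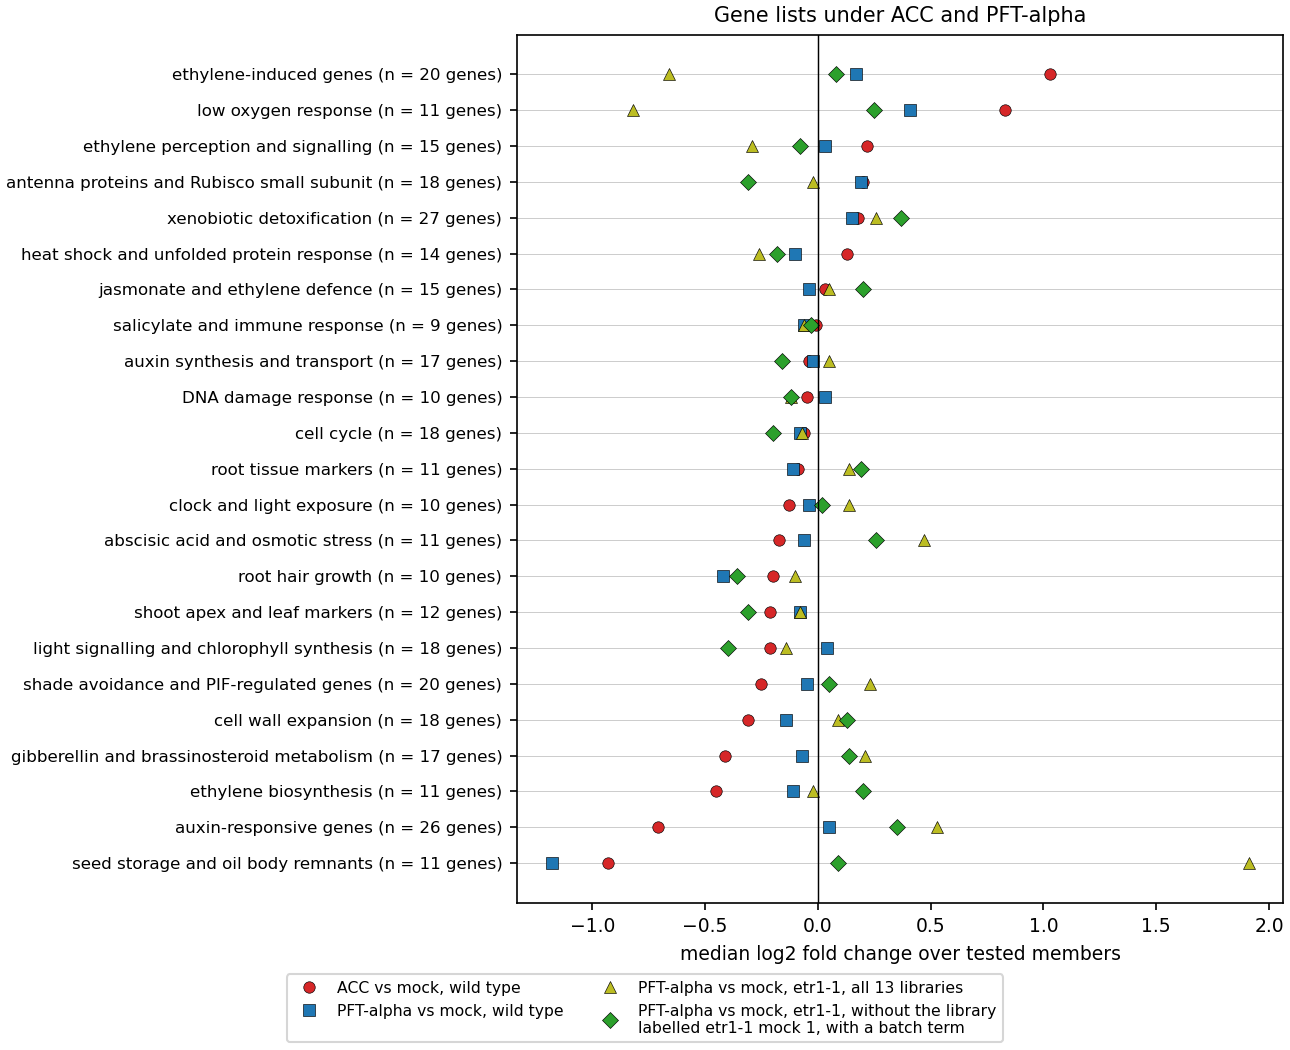
Median log2 fold change over the tested members of each of the 23 lists, under ACC and PFT-alpha in wild type and under PFT-alpha in etr1-1 with all 13 libraries and without the library labelled etr1-1 mock 1 with a batch term. Ethylene-induced genes have medians of 1.03 and 0.17 in wild type, and -0.66 and 0.08 in etr1-1.

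PFT-alpha against ACC in wild type compares both treatments directly. In the paired fit the ethylene-induced genes were lower under PFT-alpha, with RTE1 at -1.26 (SE 0.13, adjusted p = 0.00755), HLS1 at -1.17 (SE 0.12, adjusted p = 0.00755) and ORS1 at -2.47 (SE 0.21, adjusted p = 0.00331). EXPA12 measured 5.76 ± 1.59 TPM under PFT-alpha and 59.1 ± 10.8 under ACC (n = 3 each, log2 -3.16, adjusted p = 0.00162). IAA6 was higher under PFT-alpha at 27.5 ± 9.2 against 3.81 ± 1.2 TPM (2.53, SE 0.20, adjusted p = 0.00276). So were SAUR23 (1.27, adjusted p = 0.0101), BR6OX1 (1.03, adjusted p = 0.0149), HB-2 (0.77, adjusted p = 0.0209) and GLK2, a regulator of chloroplast development (1.03, adjusted p = 0.00365). EXPB1, lower under ACC, measured 17.5 ± 1.72 TPM under PFT-alpha and 3.57 ± 0.546 under ACC (2.02, adjusted p = 0.00162). For RTE1, HLS1 and ORS1 the adjusted p was 0.52 in the planned fit and 0.11 to 0.141 with the replicate block, and for IAA6 and HB-2 0.347 and 0.0338 to 0.0448. SAUR23 was called with the block (adjusted p = 0.0243), and EXPA12 and BR6OX1 (0.0663 each), EXPB1 (0.0739) and GLK2 (0.177) were not. In the planned fit these 5 stood at 0.435 to 0.712. HAT2 (0.56, adjusted p = 0.0583) and HY5, a promoter of light responses (0.58, adjusted p = 0.0686), did not pass.

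By list, 13 of 20 ethylene-induced genes fell relative to ACC in the paired fit, and 17 adjusted over the list alone (median -0.83, camera adjusted p = 4.13e-15, adjusted p = 0.637 with an estimated correlation). Of 26 auxin-responsive genes 10 rose, and 17 rose and 1 fell adjusted over the list alone (0.71, adjusted p = 1.85e-14, adjusted p = 0.637 with an estimated correlation). Gibberellin and brassinosteroid genes rose (0.28, 4 of 17, and 6 adjusted over the list alone, adjusted p = 4.81e-05, adjusted p = 0.637 with an estimated correlation). Perception genes fell (-0.31, 5 of 15, and 8 adjusted over the list alone, adjusted p = 0.000105, adjusted p = 0.782 with an estimated correlation). Shade avoidance genes rose (0.37, 3 up and 1 down of 20, and 11 and 3 adjusted over the list alone, adjusted p = 0.000185, adjusted p = 0.637 with an estimated correlation). Light signalling genes rose (0.23, 3 of 18, and 5 adjusted over the list alone, adjusted p = 0.00671, adjusted p = 0.999 with an estimated correlation). Heat shock genes fell (-0.25, 0 of 14 called by either adjustment, also adjusted over the list alone, adjusted p = 0.0196, adjusted p = 0.988 with an estimated correlation). Low oxygen genes fell too (-0.40, 0 of 11, also adjusted over the list alone, adjusted p = 0.0427, adjusted p = 0.999 with an estimated correlation, adjusted p = 0.0534 with the replicate block). With the replicate block 3 auxin-responsive genes and 1 shade gene rose and 0 members of the other 6 lists were called, and in the planned fit 0 members of the 8 lists were. Adjusted over the list alone, the planned fit called 4 ethylene-induced and 2 perception genes as lower, 11 auxin-responsive, 3 gibberellin and brassinosteroid and 2 shade genes as higher, and 0 light, heat shock or low oxygen genes. Without PFT-alpha 3 the light, heat shock and low oxygen list calls were lost (-0.13, -0.17 and -0.21), as they were without ACC 2 (-0.10, -0.15 and -0.17). The heat shock call was also lost without ACC 1 (-0.11) and the low oxygen call without PFT-alpha 2 (-0.36).

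By limma the planned fit called 0 genes between PFT-alpha and ACC (smallest adjusted p 0.0581). At an unadjusted p under 0.05 stood 1168 genes, where chance gives 1055. The block fit called 28, 18 higher and 10 lower, and the paired fit 551, 358 higher and 193 lower. The planned fit called 118 without the library labelled etr1-1 mock 1, 116 without etr1-1 mock 2, 2 without wild-type PFT-alpha 3 and 3 without wild-type ACC 1. With library weights PFT-alpha vs ACC in wild type called 1190. In 1949 genes (9.24%) the groups did not overlap, where chance gives 10% for exchangeable libraries, which these were not with replicate 3 apart.

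Fold changes under PFT-alpha and ACC in wild type were then compared across genes, which are not independent replicates. They correlated at r = 0.48 (rho 0.52). Both use the same 3 mock libraries, and 100 simulations of unchanged groups gave r = 0.50 (0.44 to 0.55). That value follows from the shared mock and equal group sizes, and the ACC effect was not simulated. The correlation therefore does not tell whether the effects are shared. The covariance was 0.0478. It lay above the simulated 0.0351 (0.0299 to 0.0416) with the spread of the paired fit and below 0.0651 (0.059 to 0.0719) with that of the planned fit. The planned fit's spread holds the replicate 3 shift that the groups share, so that simulation sets the covariance too high. Genes were simulated as independent, so both ranges can be narrower than for correlated genes. The 331 genes higher under ACC in the paired fit had a median of 0.14 under PFT-alpha in wild type, and the 828 lower genes a median of -0.21. These genes were called against the same mock libraries, so medians along the ACC direction are expected without an effect of PFT-alpha, and their size in unchanged groups was not simulated. With 0 genes called under PFT-alpha in wild type, 0 were shared with the ACC calls and 0 would be by chance. The correlation was 0.72 without wild-type mock 3 and 0.27 without wild-type PFT-alpha 3. Each of these fits weighs the replicate 3 shift unequally between groups. The 3 mock libraries were not split between both comparisons.

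Mock-treated etr1-1 against wild type asks how the mutant differs before treatment, and here the label of 1 of the 2 etr1-1 libraries is in doubt. AT4G25580 was higher in etr1-1 at 45.1 ± 4.61 TPM (n = 2) against 15.9 ± 0.993 in wild type (n = 3, log2 1.44, SE 0.18, adjusted p = 0.0343, and 1.63 with adjusted p = 0.0042 in the reduced fit). It measured 41.4 ± 5.55 under ACC in wild type. In the reduced fit, chosen after the data were seen and with etr1-1 mock 2 alone, 3 genes of the embryo or of abscisic acid responses were among those called as higher. GEA6, an embryo protein gene, measured 239.41 TPM in etr1-1 mock 2 and 10.2 ± 3.96 in wild type (log2 4.88, SE 0.89, adjusted p = 0.0319). LEA measured 65.77 and 6.55 ± 1.82 TPM (3.46, SE 0.40, adjusted p = 0.00544). The dehydrin gene RAB18 (AT5G66400), induced by abscisic acid, measured 296.72 and 62 ± 35.2 TPM (2.99, SE 0.43, adjusted p = 0.012). In the library labelled etr1-1 mock 1 the 3 genes stood at 9.74, 2.19 and 33.47 TPM. WRKY59 (-3.13, adjusted p = 0.000954), CYP708A2 (-2.15, adjusted p = 0.00714) and DR4 (-1.99, adjusted p = 0.00242) were lower. These measured 0.65, 17.88 and 31.43 TPM in etr1-1 mock 2, near wild-type mock 3 at 0.85, 29.67 and 47.89, while wild-type mock 1 stood at 14.3, 89.09 and 127.9 and mock 2 at 12.24, 97.51 and 134. For these 6 genes the adjusted p was 1 in the planned fit and 0.327 to 0.673 with the replicate block. ERF1 differed by -0.93 (adjusted p = 0.111) and ETR2 by -0.91 (adjusted p = 0.0801) in that fit.

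The planned fit called 6 genes, all higher, of which 5 are features of 120 to 210 bases. At an unadjusted p under 0.05 stood 460 genes, where chance gives 1055. Fitted fragment lengths and depths also differed between the etr1-1 and wild-type libraries, as given with the flagged results. SNOR37-2, AT4G39366, AT3G02475 and AT2G09775 were listed at 0 in all 9 wild-type libraries. In etr1-1 mock 1 and 2 they stood at 19.9 and 35.24, 29.72 and 23.86, 14.75 and 106.5, and 3.93 and 6.55 TPM. AT5G05295 was listed at 0 in the 3 mock wild-type libraries and stood at 5.08 ± 1 TPM in mock etr1-1 (n = 2). AT2G09775, AT3G02475 and AT5G05295 also overlap an antisense gene. The call of AT4G25580 was lost without any 1 of the 5 libraries (1.34 to 1.55). Those of AT3G02475 (5.36) and AT5G05295 (2.59) were lost without any 1 of the 3 wild-type libraries, and that of AT5G05295 also without the library labelled etr1-1 mock 1 (2.42). The count was 14 without the library labelled etr1-1 mock 1, 55 without etr1-1 mock 2, 3 without wild-type mock 2, 17 with the block and 282 in the reduced fit, 160 higher and 122 lower. In 2410 genes (11.4%) the groups did not overlap, where chance gives 20% for exchangeable libraries, which these were not with wild-type mock 3 apart.

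The lists called in etr1-1 mock changed with single libraries. Ethylene-induced genes were higher with all libraries (median 0.45, 19 of 20 above 0, adjusted p = 7.5e-06, adjusted p = 0.978 with an estimated correlation) and lower in the reduced fit (-0.41, adjusted p = 1.19e-05, adjusted p = 0.439 with an estimated correlation). Xenobiotic genes were higher (0.37, adjusted p = 0.00816, adjusted p = 0.999 with an estimated correlation) and at -0.08 in the reduced fit (adjusted p = 0.754). Auxin-responsive genes were lower in both, at -0.16 (adjusted p = 0.00668, adjusted p = 0.999 with an estimated correlation) and -0.28 (adjusted p = 0.00171, adjusted p = 0.617 with an estimated correlation). Abscisic acid genes were higher in both, at 0.26 (adjusted p = 0.0312, adjusted p = 0.988 with an estimated correlation) and 0.33 (adjusted p = 0.00409, adjusted p = 0.439 with an estimated correlation). With the replicate block the xenobiotic and abscisic acid calls were lost (adjusted p = 0.784 and 0.311). Without wild-type mock 3 they stood at 0.06 and -0.11, and without etr1-1 mock 2 xenobiotic genes stood at 0.45, not called, and abscisic acid genes tested as down at -0.10. Without the library labelled etr1-1 mock 1 alone, ethylene-induced genes stood at -0.29, xenobiotic genes at 0.25, not called, and auxin-responsive genes at -0.08, not called. Auxin-responsive genes were also not called without wild-type mock 1 (-0.01) or mock 2 (0.00). With the block, antenna and Rubisco genes (0.48, adjusted p = 8.8e-09) and seed storage genes (0.97, adjusted p = 0.02) were called as higher and root hair genes as lower (-0.51, adjusted p = 0.000729), where the planned fit gave 0.13, 0.20 and -0.03 (adjusted p = 0.494, 0.998 and 0.977). With an estimated correlation these block calls were lost (adjusted p = 0.721, 0.83 and 0.649). In the planned fit 0 members of the 4 lists that it called were called over all genes and 0 adjusted over the list alone, where the block called 3 auxin-responsive genes as lower.

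PFT-alpha against mock in etr1-1 asks whether the small molecule acts in the mutant. AT2G44130, a Kelch-repeat F-box protein gene with an antisense neighbour that was chosen after its values were seen, measured 112 ± 19.4 TPM in mock and 524 ± 37.1 under PFT-alpha (SD, n = 2 each, log2 2.23, adjusted p = 1 in the planned fit, 0.034 with the block and 0.122 in the reduced fit). The ethylene genes HLS1, EBF2 and ERS2 differed by -0.86, -0.61 and -0.89 with all libraries (adjusted p = 1 each) and by -0.07, -0.14 and 0.11 in the reduced fit (adjusted p = 0.974 to 0.983). The auxin-responsive genes IAA6 and IAA5 differed by 1.55 and 1.08 with all libraries and by 0.75 and 0.99 in the reduced fit (adjusted p = 1 with all libraries, and 0.974 and 0.949). GEA6 differed by 2.71 and 0.46 (adjusted p = 1 and 0.983).

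In the planned fit 9 lists were called for PFT-alpha in etr1-1, and 0 of their members were called over all genes or adjusted over the list alone. With the block 0 were called over all genes, and adjusted over the list alone 10 auxin-responsive genes rose and 1 fell, and 3 xenobiotic and 2 abscisic acid genes rose. Auxin-responsive genes rose (median 0.53, 21 of 26 above 0, adjusted p = 9.33e-09, adjusted p = 0.821 with an estimated correlation), and still did in the reduced fit (0.35, adjusted p = 2.24e-09, adjusted p = 0.439 with an estimated correlation). Xenobiotic genes rose in both (0.26, 22 of 27 above 0, adjusted p = 0.000969, adjusted p = 0.988 with an estimated correlation, and 0.37, adjusted p = 2.66e-09, adjusted p = 0.439 with an estimated correlation). Abscisic acid genes rose in both (0.47, adjusted p = 6e-06, adjusted p = 0.637 with an estimated correlation, and 0.26, adjusted p = 0.00195, adjusted p = 0.439 with an estimated correlation). Gibberellin and brassinosteroid genes rose in both (0.21, adjusted p = 0.000231, adjusted p = 0.637 with an estimated correlation, and 0.14, adjusted p = 0.021, adjusted p = 0.595 with an estimated correlation). Ethylene-induced genes fell with all libraries (-0.66, adjusted p = 6.29e-07, adjusted p = 0.856 with an estimated correlation) and rose in the reduced fit (0.08, adjusted p = 0.0232, adjusted p = 0.672 with an estimated correlation). Low oxygen genes fell with all libraries (-0.82, adjusted p = 0.00247, adjusted p = 0.988 with an estimated correlation) and were at 0.25 in the reduced fit (adjusted p = 0.087). Perception genes fell with all libraries (-0.29, adjusted p = 0.000912, adjusted p = 0.821 with an estimated correlation) and had a reduced-fit median of -0.08 that tested as up (adjusted p = 0.933). Seed storage genes (1.91, 11 of 11 above 0, adjusted p = 2.21e-05, adjusted p = 0.856 with an estimated correlation) and shade avoidance genes (0.23, adjusted p = 0.00525, adjusted p = 0.637 with an estimated correlation) rose with all libraries and were at 0.09 (adjusted p = 0.491) and 0.05 (adjusted p = 0.387) in the reduced fit. The reduced fit also called antenna and Rubisco genes (-0.31, 0 of 18 above 0, adjusted p = 6.12e-05) and light signalling genes (-0.40, adjusted p = 0.000547, adjusted p = 0.599 with an estimated correlation for both) as lower, where the planned fit gave -0.02 and -0.14 (adjusted p = 0.844 and 0.671). The xenobiotic call was lost without etr1-1 mock 2 (0.17) and the shade call without etr1-1 PFT-alpha 1 (0.15).

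The planned fit called 3 features under PFT-alpha in etr1-1, of 120 to 210 bases. At an unadjusted p under 0.05 stood 418 genes, where chance gives 1055. AT4G39366 and AT2G09775 were listed at 0 in both PFT-alpha libraries, and AT5G01145 was listed at 0 in both mock libraries and at 10.8 ± 6.8 TPM under PFT-alpha (n = 2, adjusted p = 0.00634). The call of AT2G09775 was lost without etr1-1 PFT-alpha 2 (-2.61), and that of AT5G01145 without the library labelled etr1-1 mock 1 (3.43). Calls numbered 5 with the block, 5 in the reduced fit, 200 without etr1-1 mock 2 and 5 without etr1-1 PFT-alpha 1. In 7995 genes (37.9%) the groups did not overlap, where chance gives 33.3%. PFT-alpha fold changes in wild type and etr1-1, which share no library, correlated across genes at r = -0.14 (rho -0.16), and at 0.02 without the library labelled etr1-1 mock 1.

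The genotype by PFT-alpha interaction tests whether the response differs between genotypes. By the planned fit 1 feature was called, the short AT4G39366, listed at 0 in 11 libraries. Genes at an unadjusted p under 0.05 numbered 333, where chance gives 1055. GRP5, a glycine-rich protein gene, measured 73.9 ± 6.26 and 65.5 ± 1.93 TPM in mock and PFT-alpha in wild type (n = 3 each) and 100 ± 13.3 and 197 ± 18.1 in etr1-1 (n = 2 each, interaction 1.14, SE 0.27, adjusted p = 1). COR15B, a cold-induced gene, differed by 1.32 (adjusted p = 1). ERF1 measured 1.65 ± 1.26 and 2.18 ± 0.882 TPM in wild type and 3.95 ± 4.75 and 1 ± 0.127 in etr1-1 (-1.22, SE 0.92, adjusted p = 1). Calls numbered 2 with the block, 4 in the reduced fit, 135 without etr1-1 mock 2, 3 without the library labelled etr1-1 mock 1, 2 without wild-type PFT-alpha 1 and 4 without etr1-1 PFT-alpha 1.

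The planned fit called 10 lists in no comparison. Under ACC, ethylene biosynthesis genes had a median of -0.45 (adjusted p = 0.655), auxin synthesis and transport genes -0.04 (adjusted p = 0.956), root hair genes -0.20 (adjusted p = 0.812) and jasmonate and ethylene defence genes 0.03 (adjusted p = 0.671). Ethylene biosynthesis genes moved both ways in the paired fit. Of 11, 1 rose and 3 fell over all genes, and 3 rose and 6 fell adjusted over the list alone. Salicylate and immune genes stood at -0.01 with a mean of 0.08 that tested as up (adjusted p = 0.703), DNA damage genes at -0.05 with a mean of 0.09 that tested as up (adjusted p = 0.991) and cell cycle genes at -0.06 (adjusted p = 0.624). Clock genes stood at -0.13 (adjusted p = 0.494), root markers at -0.09 (adjusted p = 0.559) and shoot apex and leaf markers at -0.21 (adjusted p = 0.134). Other fits called some of these lists. Under PFT-alpha in wild type root hair genes stood at -0.42 (adjusted p = 0.18) and were called as lower with the replicate block (adjusted p = 0.00632), in the paired fit (adjusted p = 0.0162) and in the reduced fit (adjusted p = 0.0121). Reduced-fit calls under PFT-alpha in etr1-1 were ethylene biosynthesis genes (0.20, adjusted p = 0.0186) and jasmonate and ethylene defence genes (0.20, adjusted p = 0.000263), both higher, and cell cycle genes (-0.20, adjusted p = 0.000894) and shoot apex and leaf markers (-0.31, adjusted p = 0.00717), both lower. The same 4 lists were called for the interaction in that fit, at 0.34, 0.27, -0.25 and -0.23 (adjusted p = 0.0176, 0.00108, 0.00983 and 0.0186). With an estimated correlation the adjusted p for all of these was 0.439 to 0.745.

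**Figure D4:**
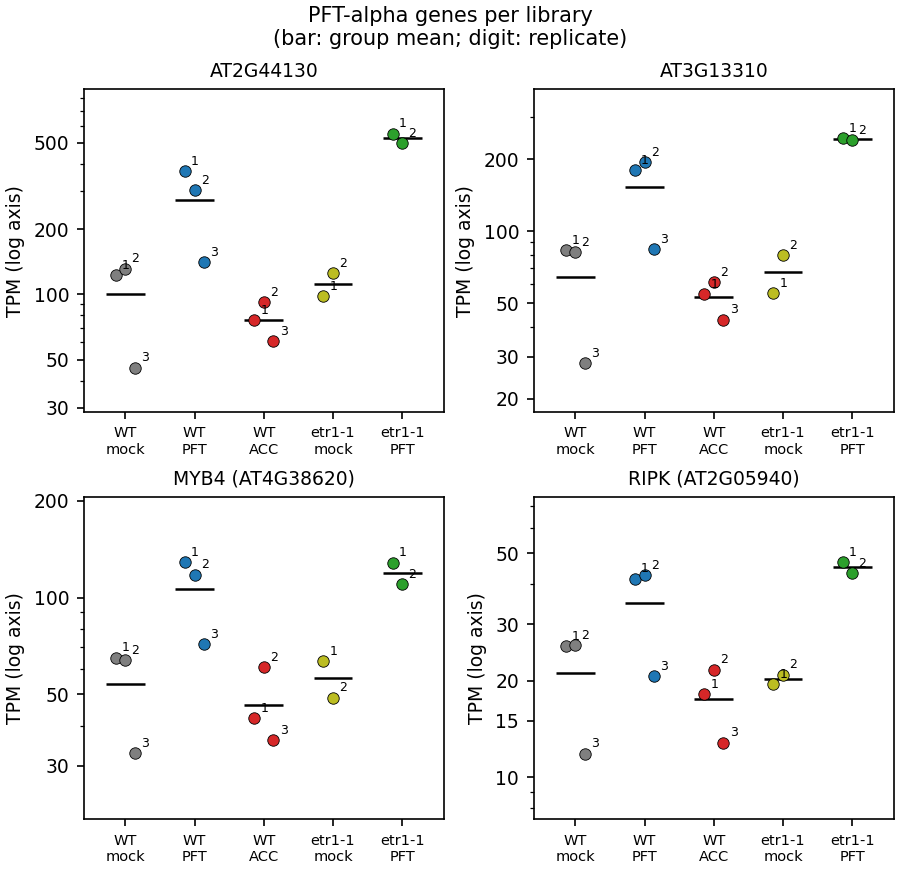
TPM per library on a log axis for AT2G44130, AT3G13310, MYB4 and RIPK, by group, with the group mean as a bar and the replicate number beside each point. AT2G44130 had means of 99.8 and 271 TPM in wild-type mock and PFT-alpha and 112 and 524 TPM in etr1-1.

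**Figure D5:**
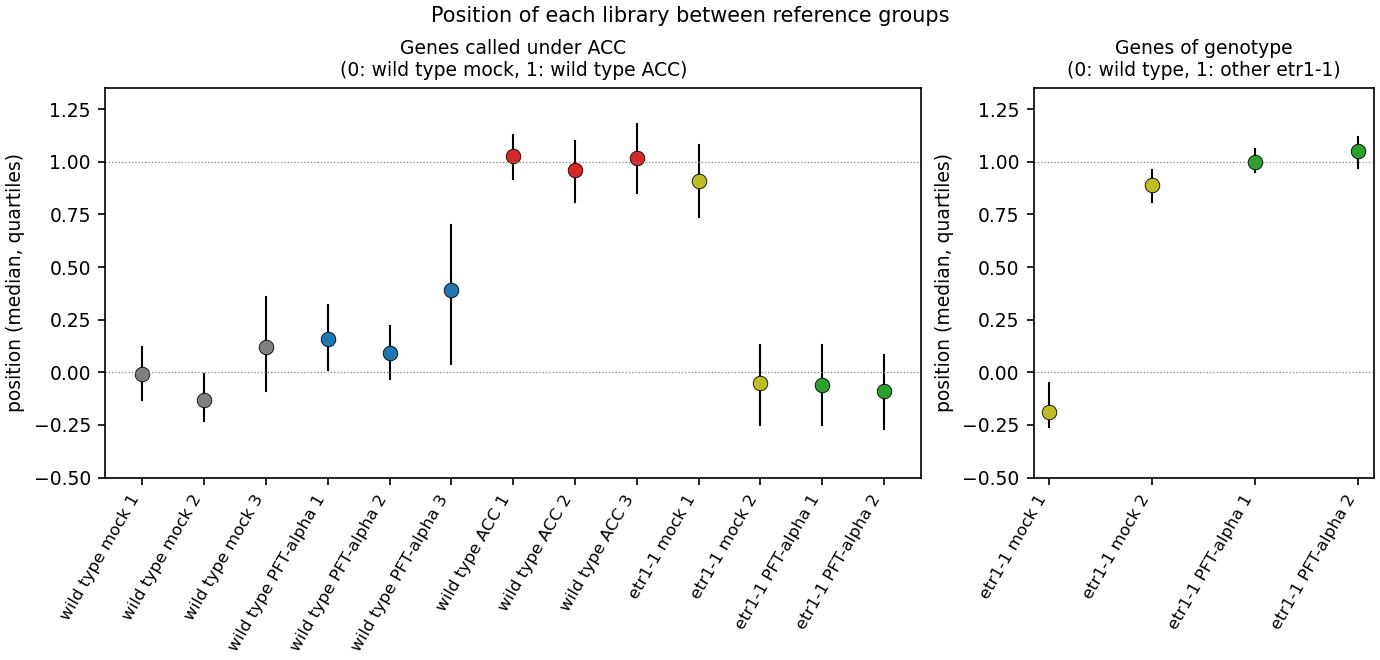
Median position of each library, with quartiles as lines. The left panel places 389 genes called at least 2-fold under ACC between mock (0) and ACC (1) in wild type, where the library labelled etr1-1 mock 1 lies at 0.91 and etr1-1 mock 2 at -0.05, and the right panel places genes of genotype between wild type (0) and the other etr1-1 libraries (1), where they lie at -0.19 and 0.89.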

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

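The interaction tests and list tests were planned, while the tests of explanations, the splits and the reduced fit were chosen after the results were seen.

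The short feature AT4G39366 drew attention because the PFT-alpha effect differed between genotypes by -4.79 log2 (adjusted p = 4.01e-05), with 29.72 and 23.86 TPM in etr1-1 mock 1 and 2 and values listed at 0 in the other 11 libraries. Gene lists (7 in all) differed between genotypes by the interaction test, and each interaction is given with its reduced-fit value. Ethylene-induced genes differed by a median of -0.89 (adjusted p = 1.94e-08, adjusted p = 0.821 with an estimated correlation) and by -0.05 in the reduced fit (adjusted p = 0.531). Seed storage and oil body genes differed by 2.85 (adjusted p = 4.18e-07, adjusted p = 0.821 with an estimated correlation) and 1.21 (adjusted p = 0.000563, adjusted p = 0.595 with an estimated correlation). Low oxygen genes differed by -1.11 (adjusted p = 2.88e-05, adjusted p = 0.856 with an estimated correlation) and -0.18 (adjusted p = 0.533). Abscisic acid genes differed by 0.53 (adjusted p = 0.000155, adjusted p = 0.782 with an estimated correlation) and 0.33 (adjusted p = 0.00732, adjusted p = 0.439 with an estimated correlation). Auxin-responsive genes differed by 0.40 (adjusted p = 0.000185, adjusted p = 0.988 with an estimated correlation) and 0.33 (adjusted p = 0.000111, adjusted p = 0.599 with an estimated correlation). Gibberellin and brassinosteroid genes differed by 0.35 (adjusted p = 0.00131, adjusted p = 0.637 with an estimated correlation) and 0.18 (adjusted p = 0.0219, adjusted p = 0.595 with an estimated correlation). Perception genes differed by -0.18 (adjusted p = 0.00322, adjusted p = 0.856 with an estimated correlation) and -0.07 (adjusted p = 0.531). In the reduced fit 8 more lists differed between genotypes, 4 of them given with the results. The others were antenna and Rubisco genes (-0.49, 0 of 18 above 0, adjusted p = 3.52e-09, adjusted p = 0.523 with an estimated correlation), light signalling genes (-0.39, adjusted p = 0.0021, adjusted p = 0.638 with an estimated correlation), xenobiotic genes (0.24, adjusted p = 0.0121, adjusted p = 0.599 with an estimated correlation) and cell wall expansion genes (0.22, adjusted p = 0.0414, adjusted p = 0.672 with an estimated correlation). The call for perception genes was also lost without wild-type mock 3 (-0.24) or PFT-alpha 1 (-0.15), and that for auxin-responsive genes without wild-type PFT-alpha 3 (0.10).

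The library labelled etr1-1 mock 1 resembled ACC-treated wild type. It correlated best with wild-type ACC 2 (0.982, against 0.954 with etr1-1 mock 2), and 389 ACC genes placed it at 0.91 between wild-type mock (0) and ACC (1), where etr1-1 mock 2 stood at -0.05. An ACC effect in true etr1-1 seedlings, or RNA of both kinds mixed, would leave the marks of the mutant in place. They were sought in 77 genes that separate the other etr1-1 libraries from wild type and did not respond to ACC. Whether these genes follow the genotype or another difference between those libraries was not tested. The arguments from them hold only if they follow the genotype. The library lay at a median of -0.19 on a scale from wild type (0) to etr1-1 (1), with an upper quartile of -0.05, which argues against an ethylene response in etr1-1, and the 75 of these genes that are higher in etr1-1 placed it at -0.07 on the linear scale, which argues against a mixture. The 3 other etr1-1 libraries, each placed on its own genes found in the same way (103, 79 and 79 higher and 3, 4 and 3 lower in etr1-1), lay at 0.89, 1.00 and 1.05, so the values are consistent with a wrong label on a library of ACC-treated wild type.

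Short features speak against that reading, and the question stays open. SNOR37-2 (19.9 TPM), AT3G02475 (14.75), AT4G39366 (29.72) and AT1G03502 (103.4) were present in the library labelled etr1-1 mock 1 and listed at 0 in all 9 wild-type libraries, and each was present in at least 1 other etr1-1 library. The same held for ath-MIR398b (32.85 TPM), AT3G07725 (23.82) and AT2G11891 (5.35). AT1G53541 went the other way, at 71.85, 18.99 and 125.8 TPM in the 3 other etr1-1 libraries and listed at 0 in this one and in wild type. AT3G09225, AT3G14452, AT4G24231 and ATMG01380 were present in this library alone. It also held 92 features under 200 bases at 5 TPM or more, beside 84 to 95 in the other etr1-1 libraries and 49 to 84 in wild type. The fragment length that best fitted the steps of low values was 210 to 230 bases in all etr1-1 libraries, this one included. It was 240 to 270 bases in wild type. Estimated depths were 25.8 to 29.3 M fragments in etr1-1 and 20.5 to 24.8 M in wild type. Both thus went with the genotype label. Whether these short features follow the genotype or how the libraries were made, and where a swap would have occurred, was not tested.

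Replicate 3 of each wild-type group stood apart on PC1. Sequencing depth lay within the range of the other libraries for 3 of 3, which argues against depth. Among 13843 genes without an overlapping gene the gap on PC1 was still 2.9 times the range of the other libraries, which argues against reads shared between overlapping genes. Root and root hair genes were lower in replicate 3 of all 3 groups for 17 of 21, or 81%, against 35.7% of all tested genes, which is consistent with a smaller share of root tissue in these samples. Root hair genes lay 1.82, 1.27 and 1.68 log2 below the other replicates in mock, PFT-alpha and ACC, and root markers 0.52, 0.72 and 0.78 below. Seed storage genes lay 1.70, 2.67 and 3.33 above them, and antenna and Rubisco genes 1.13, 1.41 and 1.06 above. Whether a smaller share of root tissue could account for rises of that size was not tested. A difference in seedling age or handling stays open, as no label gives one.

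AT2G44130, AT3G13310, MYB4 and RIPK were called as higher under PFT-alpha averaged over both genotypes, as given among the other observations. With all 13 libraries and no batch term 0 of the 4 were called (adjusted p = 0.892 to 1). In wild type alone 0 of the 4 passed (adjusted p = 0.606 to 0.636 in the paired fit). Reads shared with an overlapping gene are argued against for AT3G13310, MYB4 and RIPK, of which 0 of 3 overlap another gene. AT2G44130 lies wholly over an antisense neighbour, of which 57.5% is outside the overlap and keeps its own reads. The neighbour reached 33.1 TPM in any library, or 57.7 TPM if all its shared reads had been lost, and the smaller rise of AT2G44130, 171 TPM, was 2.96 times that. The neighbour measured 29.1 TPM in mock and 24.6 under PFT-alpha in wild type, and 27.9 and 23.8 in etr1-1. This argues against reads of that gene, while an unlisted antisense transcript within the overlap was not tested. Whether PFT-alpha acts without an ethylene-sensitive ETR1 was asked of the 20 genes with the smallest p in the paired fit, leaving out these 4. Of the 16 others, 12 had the same direction in etr1-1 in the reduced fit and 8 with all libraries, against 52.1% of all genes in the reduced fit. All 8 genes higher in wild type agreed in the reduced fit, but 4 of the 8 lower genes did not, and 3 of the other 4 stood at -0.04, -0.07 and -0.11 in etr1-1. The question stays open, with mock etr1-1 as 1 library in that fit, and no effect of PFT-alpha through other receptors was tested.

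The 6 libraries of a wild-type comparison make 10 splits, which cannot give a share under 0.1. For ACC against mock the planned fit called 2 genes, 4 of the 10 splits gave as many, and the highest other gave 2. The paired fit called 1159, 1 of the 10 splits gave as many, and the highest other gave 1. For PFT-alpha against mock both fits called 0, which all 10 splits reached, and the highest others gave 1 and 3. For PFT-alpha against ACC the planned fit called 0, which all 10 splits reached, with 1 as the highest other. The paired fit called 551, which 1 of the 10 splits reached, with 4 as the highest other. Among the 4 splits that part 3 pairs as the real one does, the highest other in the paired fit was 1 for ACC, 3 for PFT-alpha and 0 for PFT-alpha against ACC.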

How the results depend on the processing

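The paired fit, the fits with a batch term for wild-type replicate 3, and the fits without those 3 libraries or the library labelled etr1-1 mock 1 were chosen after the data were seen. Of 3961 values for 195 results on named genes, 3551 kept their side of the threshold (118 of them, called in neither fit, with another sign), 57 lost their call, 353 gained one and 0 called genes reversed. Of 906 values for 40 list calls, 723 kept the call, 168 lost it and 15 reversed. Of 249 values for 11 counts and correlations, 157 stayed, 83 moved and 9 reversed. TPM carries no counts, so depth was estimated and no count model was run. In etr1-1 each group is 2 libraries, and where 1 is left out the lone library is assumed to vary like the other groups. The paired fit has no etr1-1 libraries and gives no value for comparisons with the mutant. For results that moved the cause was not tested, except where fewer libraries or genes were tested by construction.

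PFT-alpha vs mock in wild type called 0 genes, 606 with library weights (which ranged from 0.129 to 8.75), 3 without all wild-type replicate 3 libraries and 6 without those and the library labelled etr1-1 mock 1. ACC vs mock in wild type called 2 genes, 0 with a pseudocount of 5, 0 without an intensity trend, 0 at an adjusted p under 0.01, 77 with only the compared groups, 710 with the replicate block, 1159 in the paired fit, 2142 with library weights, 661 with the batch term, 12 without wild-type replicate 3, 1958 in the reduced fit and 1827 without both. PFT-alpha vs ACC in wild type called 0, 1 each with a pseudocount of 0.1, no filter or 5 TPM, 11 with only the compared groups, 28 with the replicate block, 551 in the paired fit, 1190 with library weights, 24 with the batch term, 13 without wild-type replicate 3, 1105 in the reduced fit and 1223 without both. In etr1-1 against wild type 6 genes were called, 3 with a pseudocount of 0.1, 3 at an adjusted p under 0.01, 17 with the replicate block, 18 with the batch term, 16 without wild-type replicate 3, 282 in the reduced fit and 349 without both. PFT-alpha in etr1-1 called 3, 18 with no filter, 0 at 5 TPM, 0 with only the compared groups, 5 with the replicate block, 6 without a trend, 8 with the batch term, 13 without wild-type replicate 3, 5 in the reduced fit and 20 without both. The interaction called 1, 0 with a pseudocount of 0.1, 13 with no filter, 0 at 5 TPM, 2 with quantile scaling, 2 with the replicate block, 4 without a trend, 5 with library weights, 3 with the batch term, 2 without wild-type replicate 3, 4 in the reduced fit and 7 without both.

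The correlation of PFT-alpha effects between genotypes was -0.14, 0.02 in the reduced fit and -0.02 without wild-type replicate 3 and the library labelled etr1-1 mock 1. The 2 genes called under ACC in the planned fit, 1 of them the short ath-MIR4228, stood under PFT-alpha at a median of 0.29 along the ACC direction in wild type and of -0.13 in etr1-1. Over the 1159 genes of the paired fit the wild-type value was 0.20. In wild type the shared mock libraries push such values along the ACC direction by an amount that was not simulated. The genes called differ between settings, and in etr1-1 the value was 0.12 with no filter, -0.76 with only the compared groups and 0.01 in the reduced fit. List calls numbered 40 of 138, 62 in the reduced fit, 25 of 69 in the paired fit, 0 with an estimated correlation and 0 with fry. The replicate block changed no list call other than those given with the results. Without the library labelled etr1-1 mock 1, with the batch term and without wild-type replicate 3 in turn, ethylene-induced genes in mock etr1-1 went from 0.45 to -0.41 and -0.39, and xenobiotic genes from 0.37 to -0.08 and -0.10. Under PFT-alpha in etr1-1 perception genes went from -0.29 to -0.08, ethylene-induced genes from -0.66 to 0.08 and 0.08, and low oxygen genes from -0.82 to 0.25 and 0.25.

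Leaving out each library in turn gave 0 to 2 calls for PFT-alpha in wild type, 0 to 364 for ACC, 0 to 118 for PFT-alpha against ACC, 3 to 55 for etr1-1 against wild type, 2 to 200 for PFT-alpha in etr1-1 and 1 to 135 for the interaction. The correlation of PFT-alpha and ACC effects ranged from 0.27 (without wild-type PFT-alpha 3) to 0.72 (without wild-type mock 3), and that between genotypes from -0.21 to 0.02. Leaving out 1 wild-type library also weighs the replicate 3 shift unequally between groups, so ranges in this paragraph hold part of it. The PFT-alpha log2 fold change of the genes called under ACC, in wild type, ranged from 0.00 to 2.38 along the ACC direction. The PFT-alpha log2 fold change of the genes called under ACC, in etr1-1, ranged from -1.13 to 0.31. List calls numbered 37 to 49. Antenna and Rubisco genes ranged from -0.27 to 0.56 under PFT-alpha in wild type, and in mock etr1-1 ethylene-induced genes from -0.29 to 1.26 and abscisic acid genes from -0.11 to 0.46. Under PFT-alpha in etr1-1 perception genes ranged from -0.36 to -0.08 and ethylene-induced genes from -1.48 to 0.08. The low oxygen response, PFT-alpha vs mock in etr1-1, ranged from -1.64 to 0.25.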

Other observations

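The values averaged over genotypes, the comparison of etr1-1 with wild type under PFT-alpha and the gene ontology tests were all chosen after the results were seen.

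More genes were called under PFT-alpha when its effect was averaged over wild type and etr1-1 in the reduced fit. The etr1-1 mock mean given here for AT2G44130 includes the library labelled etr1-1 mock 1 (98.17 TPM), which that fit leaves out. AT2G44130, a Kelch-repeat F-box protein gene of a family that marks phenylpropanoid enzymes and cytokinin response regulators for degradation, measured 99.8 ± 46.9 TPM in mock and 271 ± 118 under PFT-alpha in wild type (SD, n = 3 each). In etr1-1 it measured 112 ± 19.4 and 524 ± 37.1 TPM (n = 2 each, average log2 1.75, SE 0.17, adjusted p = 0.0143, 0.0195 to 0.075 leaving out 1 more library). AT3G13310, a DNAJ protein gene, rose by 1.45 (adjusted p = 0.0252, range 0.0195 to 0.135). MYB4, a repressor of phenylpropanoid genes, rose by 1.13 (adjusted p = 0.0252, range 0.0646 to 0.14), and the kinase gene RIPK by 0.89 (adjusted p = 0.0252, range 0.0549 to 0.135). With all 13 libraries and the batch term the adjusted p values were 0.00293, 0.00788, 0.0215 and 0.00616, and with all 13 and no batch term the 4 calls were lost (adjusted p = 0.892 for AT2G44130 and 1 for the others). In wild type alone none of the 4 genes was called (adjusted p = 0.606, 0.622, 0.622 and 0.636 in the paired fit), nor in etr1-1 alone (adjusted p = 0.122, 0.395, 0.395 and 0.248 in the reduced fit), though AT2G44130 was in etr1-1 with the block (adjusted p = 0.034). Their interaction with genotype had an adjusted p of 0.984 each, and under ACC in wild type they stood at 76.1, 53, 46.4 and 17.6 TPM. Another Kelch-repeat F-box gene, AT3G59940, which also lies over an antisense gene, differed by 1.00 (adjusted p = 0.107, and 0.0426 with all 13 libraries and the batch term), and AT1G80440 and AT1G15670 by 0.36 and 0.39 (adjusted p = 0.923 and 0.831, and 0.909 each with all 13).

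In all 7 genes were called on average, 4 higher and 3 lower (1019 at an unadjusted p under 0.05), and 2 to 7 leaving out 1 more library. The 3 lower ones are short features. With all 13 libraries 11 were called with the batch term and 1, the short AT4G39366, without it. Xenobiotic detoxification genes rose on average (median 0.25, 23 of 27 above 0, adjusted p = 2.63e-12, adjusted p = 0.294 with an estimated correlation), with 0 members called over all genes and 4 adjusted over the list alone. As lists, auxin-responsive genes rose by 0.26 (adjusted p = 1.86e-09, adjusted p = 0.444 with an estimated correlation), ethylene-induced genes by 0.12 (adjusted p = 1.08e-05, adjusted p = 0.444 with an estimated correlation) and low oxygen genes by 0.33 (adjusted p = 0.000394, adjusted p = 0.589 with an estimated correlation). Jasmonate and ethylene defence genes rose by 0.07 (adjusted p = 0.00685) and abscisic acid genes by 0.10 (adjusted p = 0.0196, adjusted p = 0.444 with an estimated correlation for both). Cell cycle genes fell by 0.12 (adjusted p = 0.00547, adjusted p = 0.589 with an estimated correlation), light signalling genes by 0.19 (adjusted p = 0.0109, adjusted p = 0.678 with an estimated correlation) and root hair genes by 0.39 (adjusted p = 0.0196, adjusted p = 0.589 with an estimated correlation). Of the members of these 8 lists 0 were called over all genes and 0 adjusted over the list alone. The auxin average came mostly from etr1-1, at 0.35 against 0.05 in wild type.

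Gene ontology terms were tested among genes called in the paired fit. Of 270 annotated genes higher under ACC, 26 belonged to ethylene-activated signaling (2.66 by chance, adjusted p = 8.6e-15). Of 621 lower genes, 34 belonged to the response to auxin (10 by chance, adjusted p = 4.71e-07), 10 to wax biosynthesis (0.864, adjusted p = 2.94e-06) and 17 to unidimensional cell growth (3.68, adjusted p = 7.1e-05). Cell wall organization (32 against 12.2, adjusted p = 0.000259) and shade avoidance (5 against 0.601, adjusted p = 0.0295) were also over-represented.

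Under PFT-alpha, where no label is in doubt, etr1-1 differed from wild type by 6 genes in the planned fit and 813 in the reduced fit, 495 higher and 318 lower. Of 381 annotated higher genes, 39 belonged to the response to abscisic acid (8.75 by chance, adjusted p = 1.4e-11) and 29 to water deprivation (7.44, adjusted p = 4.71e-07). Terms of the embryo and seed were called as well, with 8 in lipid storage (0.576, adjusted p = 3.49e-05), 10 in seed germination (1.7, adjusted p = 0.00186), 9 in seed development (1.54, adjusted p = 0.00481) and 5 in seed maturation (0.599, adjusted p = 0.0324), as was light harvesting with 5 (0.576, adjusted p = 0.0295). Of 256 lower genes, 18 belonged to the cellular response to hypoxia (3.72, adjusted p = 2.61e-05) and 9 to the response to ethylene (1.53, adjusted p = 0.00485). The libraries of the genotypes also differed in fitted fragment length and depth, as given with the flagged results. RAB18 (AT5G66400) measured 320 ± 60.1 TPM in etr1-1 (n = 2) and 60.5 ± 68 in wild type (n = 3) under PFT-alpha. The count was 100 without the library labelled etr1-1 mock 1 and 100 without etr1-1 mock 2 in the planned fit.

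Reduced-fit lists in mock etr1-1 that the planned fit did not call were antenna and Rubisco genes, higher by a median of 0.69 (adjusted p = 1.77e-12, adjusted p = 0.439 with an estimated correlation, 4 of 18 called, 14 adjusted over the list alone), and seed storage genes, higher by 2.72 (adjusted p = 3.02e-08, adjusted p = 0.439 with an estimated correlation, 2 of 11 called, 6 adjusted over the list alone). Low oxygen genes were lower by 1.15 (adjusted p = 4.63e-06, adjusted p = 0.595 with an estimated correlation, 0 of 11 called, 9 adjusted over the list alone). Also higher were light signalling (0.48, adjusted p = 1.61e-05), cell cycle (0.27, adjusted p = 0.00812), clock (0.20, adjusted p = 0.0156) and shoot apex and leaf genes (0.24, adjusted p = 0.0186). Perception (-0.18, adjusted p = 0.0036), jasmonate and ethylene defence (-0.24, adjusted p = 0.0169), root hair (-0.45, adjusted p = 0.0456) and ethylene biosynthesis genes (-0.28, adjusted p = 0.0467) were also lower. With an estimated correlation the adjusted p of these 8 lists was 0.439 to 0.672. The seed storage gene SESA1 measured 10.19 TPM in etr1-1 mock 2 against 15.35, 32.64 and 171.7 in wild-type mock. These list calls rest on 1 etr1-1 library. In wild-type mock, replicate 3 lay above the other replicates in antenna and Rubisco (1.13), seed storage (1.70) and light signalling genes (0.95). It lay below them in low oxygen (-0.76) and root hair genes (-1.82). Of the lists named here clock genes alone went the other way there (-0.32). Whether etr1-1 mock 2 shares that shift was not tested.

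In 3 pairs of tested genes on opposite strands the share of the pair's TPM moved between 0 and 100% across libraries, AT1G23050 with AT1G23052, LHB1B2 with AT2G08665 and AT4G36808 with GGPPS1, so their single values are uncertain.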
